A study of Mus musculus with 21 samples.

How the data were processed

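Cumulus-oocyte complexes (COCs), each an oocyte with the cumulus granulosa cells around it, were taken from ovaries of wild-type mice and matured in culture with epidermal growth factor and 5% serum at 37 °C under 5% CO2, per the labels' protocols. The culture held 10 µM of a proprotein convertase inhibitor (PCI) or its solvent, DMSO (CTL). RNA was sequenced from COCs before culture (START) and after 4, 8 and 12 h, which gave 7 groups of 3 replicates that the labels call biological, 21 libraries in all. The libraries were made with a stranded, poly(A)-selecting kit.

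The deposited values are raw counts per gene, in 1 table of 56980 genes and 21 columns, and each column was matched to its sample by name. Reads were trimmed with cutadapt, aligned with STAR to mm39 and counted with HTSeq, per the submitters' processing notes; versions, the annotation release and HTSeq's strand setting are not given in the sources used here. Gene identifiers, symbols, positions on mm39 and biotypes were taken from the deposited table, so positions are those of whole genes, not of exons. HTSeq's handling of reads that fit several genes is likewise not given. Counts of genes with related copies (Akr1c14 and Akr1c18, Aldh1a7 and Aldh1a1, Adh1 and Adh7, Csf2rb, Magea13, H2-Ab1) are uncertain to that extent. Arhgap27 and Plekhm1 are adjacent without overlap, and their counts are uncertain as to reads that run past a gene end.

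The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, which left 18192 genes holding at least 99.92% of the counts of every library, and libraries were scaled with TMM factors. A model with a mean per group was fitted to all 21 libraries (14 residual degrees of freedom), and each comparison was tested with edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 18192 genes. Genes with an adjusted p under 0.05 are called higher or lower; every adjusted p of a gene comes from this test unless another tool is named. Log2 fold changes are those of the fit at edgeR's default prior count. Their standard error (SE) is the size of the log2 fold change over the square root of its F statistic. Log2 CPM values used a prior count of 2. CPM (edgeR's cpm function) are counts relative to the TMM-scaled library size, given as mean ± SD over 3 libraries. For a gene with no count in a group, the fold is a lower limit against 3 counts over that group, and with 1 to 3 counts the ratio has an exact 95% interval for counting error only.

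Total counts were 19458618 to 37491828 per library. The biological coefficient of variation was 29.5%, and the median SE of a log2 fold change between PCI and CTL was 0.324 at 4 h, 0.325 at 8 h and 0.322 at 12 h. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 22.9 to 272), so all libraries were counted. In counts simulated from the real means and library sizes (17758 genes), 200 genes were changed between PCI and CTL at 8 h, and 20 more were raised as a list. Of genes changed 2-fold 30% were recovered, and of genes changed 4-fold 85%. With the 20 counted as true changes, 3.25% of the 123 calls were false. The simulated libraries were independent, with the same spread per gene in all groups. START and PCI at 4 h spread more than the other real groups, so these shares may not hold there.

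The comparisons were PCI against CTL at each time and as the mean over the 3 times, the change of the PCI effect with time, and CTL at each time against START. Of 39 lists of genes, 38 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The lists hold genes of the cumulus matrix, signalling, metabolism, stress and the cell cycle, and markers of oocytes, theca cells, stroma, endothelium, leukocytes and red blood cells; of the red cell markers only 1 of 5 was measured, so that list was not tested. Sets of the 200 genes with the smallest p that rose or fell in CTL by 1 time were tested for the PCI effect at the other times, so that set and test share no library. The share of oocyte RNA, estimated through marker genes, was compared with exact permutation tests.

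The text names a panel fixed in advance (Has2, Ptgs2, Tnfaip6, Ptx3, Areg, Ereg, Gdf9, Bmp15, Furin, Pcsk5, Pcsk6 and Amh); for each PCI time the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in either group, no overlap of the libraries and an established symbol; the 6 largest of each for CTL times; up to 4 members with the smallest p of each list discussed; and the 6 genes with the smallest p for the change with time. Groups, comparisons, lists, this rule and all alternatives but those marked as added were chosen before the data were examined.

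Replicate numbers recur in every group. Deviations from the group means of same-numbered PCI and CTL libraries correlated at 0.32, 0.52 and 0.14 at 4 h and at 0.17, 0.11 and 0.27 at 8 h, all over the minimum of 0.1 set for treating the numbers as pairs. At 12 h the correlations were 0.23, 0.042 and 0.17, not all over that minimum, so the numbers there were not treated as pairs. These correlations were still all over those of differently numbered libraries (highest -0.016), so pairing at 12 h stays open. Differently numbered libraries reached 0.24 at 4 h and 0.13 at 8 h. Between CTL and START some correlations of same-numbered libraries were negative, so there the libraries share only a number. The labels give no batch or date. The main tests used no pairs at any time. Pairs entered only the sign flips of the oocyte ratio at 4 and 8 h and the replicate block, both alternatives. That block was a term for the replicate number over all 21 libraries, so it also tied the 12 h and START libraries by number.

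Alternatives were RLE factors, library size alone, no filter, a replicate block, only the groups compared, DESeq2 1.42.0, an estimated correlation for lists, sets of 100 and 400 genes, and each library left out in turn; a covariate for the oocyte score of each library, and exact sign flips of the oocyte ratio within same-numbered pairs at 4 and 8 h, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No column was left out. Isoforms and exon positions were not analysed here. The rule for named genes also took 1 gene at 8 h that is not reported here.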

Results

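The data are RNA-seq counts from 21 libraries of mouse COCs, in 7 groups of 3 biological replicates: COCs before culture (START, 0 h), and COCs matured for 4, 8 and 12 h with epidermal growth factor. The medium held DMSO (CTL) or 10 µM of an inhibitor of proprotein convertases (PCI). These enzymes, among them furin, cut precursor proteins into their mature forms. The study asks whether they regulate the cumulus matrix and cumulus cell behaviour by way of the oocyte factor GDF-9. Libraries held 19458618 to 37491828 counts. The first principal component of the 1000 most variable genes took 57.1% of the variance and followed time in culture. Mean scores were -77.7 ± 11.5 in START and -40.4 ± 4.18, 12 ± 14.4 and 56.5 ± 2.92 in CTL at 4, 8 and 12 h (SD, n = 3). PCI libraries scored -36.6 ± 16.4, 32.5 ± 7.84 and 53.6 ± 5.92. The third component (4.23%) separated the arms, more widely late in culture. It was at -1.94 ± 3.72 in CTL and -10.2 ± 2.32 in PCI at 4 h. The scores were 20.6 ± 1.75 and -11.8 ± 8.64 at 8 h and 15.1 ± 3.48 and -15.4 ± 3.73 at 12 h. Replicates spread more in START and in PCI at 4 h (median SD of log2 CPM 0.442 and 0.438) than in the other groups (0.23 to 0.279).

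**Figure D1:**
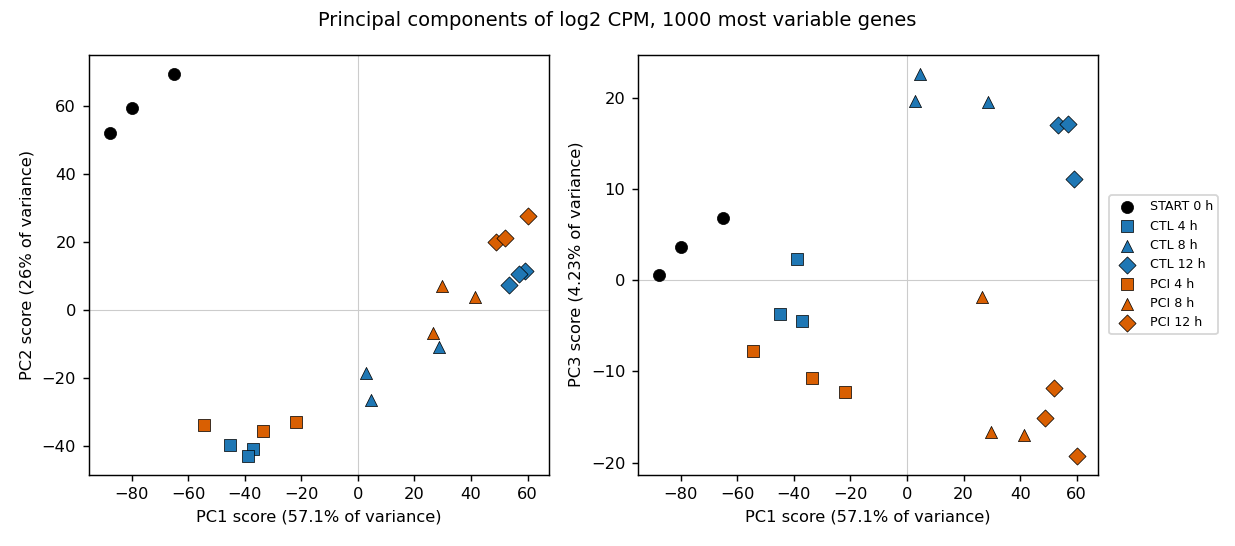
Scores of the 21 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM over the 1000 most variable genes; colour marks the arm and shape the time. The first axis holds 57.1% of the variance and orders the libraries by time, and on the third axis (4.23%) CTL and PCI libraries at 8 and 12 h lie on opposite sides of 0.

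Control COCs were first compared with COCs before culture to describe maturation in this system. Genes of the expanding cumulus matrix rose strongly by 4 h. Ptx3, a pentraxin that holds the hyaluronan matrix together, had 0.997 ± 0.366 CPM in START and 4173 ± 827 CPM in CTL at 4 h (SD, n = 3). Has2, the hyaluronan synthase of cumulus cells, had 13.4 ± 1.45 and 1330 ± 257 CPM. Tnfaip6, which links proteins to hyaluronan, and Ptgs2, the inducible prostaglandin synthase, rose by 8.54 ± 0.34 and 8.30 ± 0.36 on the log2 scale (± SE). Of the 10 measured genes of this list, 9, 8 and 8 rose at 4, 8 and 12 h (9, 8 and 8 adjusted over the list alone), and 1 fell at 12 h. The list was higher at all 3 times (camera adjusted p = 3.02e-09, 8.26e-06 and 0.00012, and adjusted p = 0.0145, 0.0306 and 0.0772 with an estimated correlation). The EGF-like ligands Areg and Ereg, which carry the ovulatory signal to cumulus cells, rose by 8.90 ± 0.66 and 10.38 ± 0.92 at 4 h. The list of EGF ligands and receptors was not called (adjusted p = 0.119). Matrix and basement membrane genes rose as well, 11, 9 and 13 of 18 (11, 9 and 14 adjusted over the list alone). The list had adjusted p = 4.12e-05, 0.000109 and 5.9e-06, and adjusted p = 0.0313, 0.0306 and 0.0205 with an estimated correlation. Among them Col4a1, a collagen IV chain, rose by 4.96 ± 0.37, 6.26 ± 0.39 and 7.11 ± 0.41. Spp1, the secreted phosphoprotein osteopontin, reached 654 ± 140, 5098 ± 923 and 16810 ± 1470 CPM.

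Genes of the unexpanded cumulus fell over the same hours. Slc38a3, an amino acid transporter of cumulus cells, fell by 5.83 ± 0.52, 6.84 ± 0.55 and 6.34 ± 0.54 on the log2 scale at 4, 8 and 12 h, and Fshr, the receptor for follicle-stimulating hormone, by 3.82 ± 0.31, 5.71 ± 0.34 and 4.76 ± 0.33. Of 10 such genes 8, 8 and 7 fell (9, 8 and 7 adjusted over the list alone). This list had adjusted p = 1.32e-05, 0.000125 and 0.000401 (adjusted p = 0.0313, 0.0611 and 0.0942 with an estimated correlation). Genes of DNA replication and the G1/S transition fell too, 11, 13 and 14 of 18 (11, 13 and 14 adjusted over the list alone). Here adjusted p = 0.000911, 0.00245 and 1.14e-05, and adjusted p = 0.0234, 0.0306 and 0.00464 with an estimated correlation. The helicase subunit gene Mcm3 fell by 1.43 ± 0.16, 1.54 ± 0.16 and 1.92 ± 0.16. Among proprotein convertase genes, Pcsk6 rose by 3.61 ± 0.26 at 4 h, Furin by 1.17 ± 0.20 at 4 h and 1.96 ± 0.20 at 12 h, and Pcsk5 by 3.38 ± 0.34 at 12 h. The list of 8 convertases was not called at any time (adjusted p = 0.341, 0.151 and 0.0802). Of 30 oocyte genes 20 fell by 12 h (21 adjusted over the list alone), with adjusted p = 2.03e-06, and adjusted p = 0.575 with an estimated correlation. Among them Npm2 and the zona pellucida gene Zp3 fell by 5.30 ± 0.57 and 5.04 ± 0.60.

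The largest rises at 4 h were in Stmn2 (no count in START, at least 746-fold), Spp1 (12.46 ± 0.68 on the log2 scale), Kcnk10 (1 count in START; ratio 6550, 95% interval 1170 to 259000), Ptx3 (12.02 ± 0.51), Pdyn (at least 468-fold) and Procr (11.46 ± 0.52). Aldh1a3, an enzyme of retinoic acid synthesis, joined them at 8 h (11.58 ± 0.49) and the neurotensin gene Nts at 12 h (11.31 ± 0.89). Csf2rb and Anxa8 were at least 731-fold and 260-fold higher at 12 h. The largest falls at 4 h were in Mmd2, Fndc5, Kctd14, Gsg1l, Vstm4 and Lnx1 (log2 fold changes -7.81 ± 0.54 to -6.24 ± 0.62). Later ones took in Ndufa4l2, Slfn4, Aldh1a7 and Mybpc3 at 8 h (-7.77 ± 0.97 to -7.03 ± 0.89) and Mybpc3 and Cpsf4l at 12 h (-9.01 ± 1.03 and -8.83 ± 1.04). At 12 h Aldh1a7, Magea13 and Meikin were 576-fold (95% interval 159 to 4770), 358-fold (122 to 1740) and 318-fold (87.6 to 2630) lower, on 2, 3 and 2 counts in CTL. In all, edgeR called 5734 of 18192 genes at 4 h (2950 higher, 2784 lower), 7506 at 8 h (3766 and 3740) and 9286 at 12 h (4559 and 4727). Scaled by library size alone, 2579 were higher and 3489 lower at 4 h, which turned the balance. With the added oocyte score covariate 6045 genes were called at 12 h, of which 3897 were among the 9286. The 3 comparisons share the START libraries.

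After 4 h, the fit to all 21 libraries called 24 genes between COCs with PCI and control COCs. With only the 6 libraries of this time edgeR called 0 (611 at an unadjusted p under 0.05). Among the 24 were genes that answer to BMP and TGF-beta signals. Smad7 (ENSMUSG00000025880, mm39 chromosome 18, 75500600 to 75529006), which encodes an inhibitory SMAD, was at 46.9 ± 9.1 CPM in PCI and 129 ± 23.6 CPM in CTL (SD, n = 3 each). It fell by 1.46 ± 0.18 on the log2 scale (± SE, adjusted p = 0.00261). Id4 (ENSMUSG00000021379, chromosome 13, 48414704 to 48419502) and Id1, inhibitors of basic helix-loop-helix factors, fell by 2.12 ± 0.33 and 1.19 ± 0.21. Nog, which encodes the BMP antagonist noggin, fell by 2.33 ± 0.40. The growth and stress genes Myc, Jun and Gadd45g fell by 1.32 ± 0.24, 1.08 ± 0.18 and 2.01 ± 0.38. The integrin gene Itga5 and the receptor gene Pdgfrb fell by 1.07 ± 0.20 and 1.95 ± 0.37. Il23a, a cytokine subunit, Ak1, an adenylate kinase, Olfm2 and Arhgap27 fell by 2.38 ± 0.39, 2.40 ± 0.45, 2.19 ± 0.43 and 1.83 ± 0.33. Sgk1, a hormone-induced kinase, rose from 296 ± 36 to 1036 ± 308 CPM, and Tmem86a from 28.9 ± 6.46 to 176 ± 130 CPM. These were the 2 genes called higher, against 22 called lower (24 in all, while 908 genes had an unadjusted p under 0.05). Without PCI replicate 2, 30 were higher and 24 lower, which turned the balance. Without any other single library of this time 0 were higher, and DESeq2 called 33 higher and 81 lower.

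The matrix genes of the panel lay lower in PCI at 4 h without passing the test. Has2 was at 751 ± 210 CPM in PCI and 1330 ± 257 CPM in CTL (log2 fold change -0.83 ± 0.35, adjusted p = 0.816), and Tnfaip6 at 2447 ± 620 and 4526 ± 1640 CPM (-0.89 ± 0.24, 0.279). Ptgs2 was at 1734 ± 388 and 2803 ± 966 CPM (-0.69 ± 0.26, 0.659) and Ptx3 at 2830 ± 733 and 4173 ± 827 CPM (-0.56 ± 0.32, 1). As a list, the 10 expansion genes were lower at 4 h (0 called over all genes by edgeR, 4 at an unadjusted p under 0.05, and 1 adjusted over the list alone). This gave adjusted p = 0.00579 (adjusted p = 0.166 with an estimated correlation). That call was lost without CTL 4 h replicate 1 (adjusted p = 0.173) or PCI 4 h replicate 2 (0.299), the range over all alternatives being 0.000866 to 0.299. Areg, Ereg, Gdf9, Bmp15, Furin, Pcsk5, Pcsk6 and Amh had log2 fold changes of 0.44, 0.87, 0.10, 0.12, -0.21, 0.23, -0.19 and -0.34 (SE 0.19 to 1.11), each with an adjusted p of 1.

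Among the lists at 4 h, 3 signalling lists were lower in PCI with either correlation. Of 12 genes of the BMP-SMAD1/5 arm, 3 fell, Smad7, Id1 and Id4 (6 adjusted over the list alone). The mean log2 fold change was -0.919 (adjusted p = 2.73e-13, and 0.00188 with an estimated correlation). Of 13 genes of the TGF-beta-SMAD2/3 arm, 1 fell, Smad7, which both lists hold (4 adjusted over the list alone). The mean was -0.529 (adjusted p = 1.96e-08 and, with an estimated correlation, 0.00188). Of 22 ligands, receptors and inhibitors of the TGF-beta family, Nog fell (3 adjusted over the list alone, adjusted p = 1.58e-05 and, with an estimated correlation, 0.00188). The 22 immediate-early and ERK feedback genes were lower as a list, with Jun and Myc called (3 adjusted over the list alone). Their adjusted p was 6.81e-06, and adjusted p = 0.083 with an estimated correlation. These 4 lists kept their calls with any library left out. The count of genes rested on single libraries: it was 3 without PCI replicate 1, 5 without PCI replicate 3, 4 without CTL replicate 1, 4 without CTL replicate 3 and 54 without PCI replicate 2. Smad7 kept its call each time, while the other called genes named here lost theirs in at least 3 of the 6 leave-outs. With the replicate block Itga5 and Olfm2 did not pass (adjusted p = 0.0574 each). With only the 6 libraries of this time in the fit, edgeR called 0 genes (611 at an unadjusted p under 0.05), and with all libraries DESeq2 called 114. Such fits to 6 libraries called 845 genes at 8 h and 767 at 12 h. The main fit takes each gene's spread from all 7 groups, most of them tighter than PCI at 4 h. It may thus understate the spread behind the calls at 4 h.

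**Figure D2:**
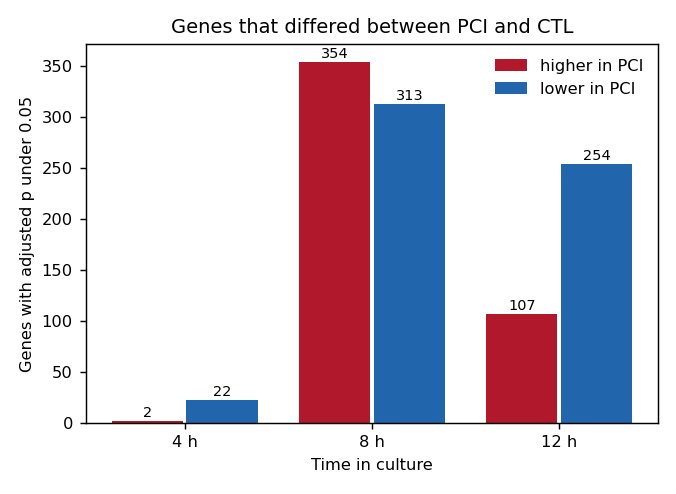
Number of genes called higher (red) and lower (blue) in PCI than in CTL at each time, of 18192 tested with edgeR (adjusted p under 0.05, 3 libraries per group). The counts were 2 and 22 at 4 h, 354 and 313 at 8 h, and 107 and 254 at 12 h.

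By 8 h the matrix genes Has2 and Ptx3 were lower in PCI. Has2 (ENSMUSG00000022367, chromosome 15, 56529023 to 56557935) was at 113 ± 74 CPM in PCI and 651 ± 155 CPM in CTL (SD, n = 3 each). It fell by 2.52 ± 0.36 on the log2 scale (± SE, adjusted p = 0.000752). Ptx3 (ENSMUSG00000027832, chromosome 3, 66127331 to 66133226) was at 770 ± 359 and 2939 ± 347 CPM and fell by 1.93 ± 0.33 (adjusted p = 0.00216). Ptges, the prostaglandin E synthase, fell by 1.77 ± 0.26. Vcan and Hapln1, which encode the proteoglycan versican and its link protein, rose by 1.45 ± 0.30 and 3.57 ± 0.77, Hapln1 from under 1 CPM. The list of 10 expansion genes, with 2 called higher and 3 lower, was not called (adjusted p = 0.319). Tnfaip6 and Ptgs2 did not pass (log2 fold changes -0.22 ± 0.24 and -0.03 ± 0.26). Areg, Ereg, Gdf9, Bmp15, Furin, Pcsk5, Pcsk6 and Amh had 0.95, 0.94, 0.03, 0.02, -0.39, 0.77, 0.24 and -1.80, with adjusted p of at least 0.235. In total 667 genes were called, 354 higher and 313 lower (336 and 371 when scaled by library size alone). The count was 252 without PCI replicate 1, 330 without PCI replicate 2, 256 without CTL replicate 1 and 414 without CTL replicate 3, and DESeq2 called 1084. Without CTL replicate 3, 164 were higher and 250 lower, which turned the balance, and without CTL replicate 1, 127 and 129. In the other leave-outs more were higher than lower.

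Among the largest rises at 8 h were those of Igfbp5 and Cyp11a1. Igfbp5 (ENSMUSG00000026185, chromosome 1, 72897091 to 72914043), which encodes a binding protein of insulin-like growth factors, rose from 6.56 ± 4.18 CPM in CTL to 363 ± 171 CPM in PCI (log2 fold change 5.79 ± 0.76). Cyp11a1 (ENSMUSG00000032323, chromosome 9, 57913694 to 57934306), the side-chain cleavage enzyme that starts steroid synthesis, rose from 1.65 ± 1.6 to 29 ± 1.88 CPM (4.12 ± 0.81). The alcohol dehydrogenase genes Adh1 and Adh7 rose by 6.07 ± 1.17 and 4.76 ± 1.02, and the serine protease gene Prss35 by 4.97 ± 0.70. The transcription factor gene Msc rose by 4.55 ± 0.86, Lrrn3 by 3.82 ± 0.58 and the steroid-converting aldo-keto reductase gene Akr1c14 by 3.63 ± 0.65. The largest falls were in H2-Ab1, a class II histocompatibility gene (-5.06 ± 0.93), Trim66 (-3.88 ± 0.75), Prss46 (-3.86 ± 0.59) and Stra6, the retinol uptake receptor gene (-3.76 ± 0.81). Next came Pkd1l2 (-3.59 ± 0.90), Trim9 (-3.19 ± 0.56) and the heparan sulfate sulfotransferase gene Hs3st3a1 (-3.13 ± 0.53). Of these genes, Adh7, Stra6 and Pkd1l2 lost their calls when some library was left out (highest adjusted p = 0.0609 without CTL replicate 3, 0.0819 without PCI replicate 1 and 0.128 without PCI replicate 1).

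Steroid synthesis was the list with the smallest p at 8 h. Of its 13 genes, 4 rose (5 adjusted over the list alone), with a mean log2 fold change of 1.26. It had adjusted p = 6.84e-07, and adjusted p = 0.269 with an estimated correlation. The 3 measured theca markers, of another steroid-making cell type, were higher as a list at 8 h too (mean 1.04, adjusted p = 0.0155, and adjusted p = 0.252 with an estimated correlation). The 4 genes called were Cyp11a1, Akr1c18 (3.12 ± 0.79), the nuclear receptor gene Nr5a2 (1.45 ± 0.24) and the electron carrier gene Fdx1 (1.16 ± 0.24). Of 13 regulators induced at ovulation, Fosl2, Nr4a1 and Nrip1 rose (7 adjusted over the list alone), by 1.58 ± 0.25, 1.08 ± 0.27 and 0.63 ± 0.17. For this list adjusted p = 4.68e-06, and adjusted p = 0.252 with an estimated correlation. Of 10 genes of mural granulosa cells, which line the follicle wall, Cyp11a1 rose, as did Prlr, the prolactin receptor gene, by 1.53 ± 0.36 (2 adjusted over the list alone). Their list had adjusted p = 0.013, and adjusted p = 0.307 with an estimated correlation. The 21 lysosomal genes were higher as a list, with Grn called at 0.65 ± 0.14 (3 adjusted over the list alone). Here adjusted p = 0.000271, and adjusted p = 0.307 with an estimated correlation. The 22 genes of cholesterol synthesis were higher too, with 0 called by edgeR (5 at an unadjusted p under 0.05, 2 adjusted over the list alone). That list had adjusted p = 0.00708, and adjusted p = 0.618 with an estimated correlation.

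The BMP-SMAD1/5 list was lower at 8 h, with Smad7, Id4, Smad6 and Id1 called, at -1.42 ± 0.18, -2.01 ± 0.33, -1.24 ± 0.25 and -0.93 ± 0.21 (6 adjusted over the list alone). The list's adjusted p = 1.96e-05, and adjusted p = 0.184 with an estimated correlation. The SMAD2/3 list was not called (adjusted p = 0.0552), but was with the replicate block (0.0305). Over all alternatives its adjusted p ran from 0.0305 to 0.307. The oocyte list was lower, with 0 of 30 genes called by edgeR (2 at an unadjusted p under 0.05, 0 adjusted over the list alone). This oocyte list had adjusted p = 0.0476, adjusted p = 0.797 with an estimated correlation, and 0.0543 with the block (range 0.00107 to 0.797). Without CTL replicate 1, CTL replicate 3 or PCI replicate 1 it was 0.0547, 0.59 and 0.492. With the added oocyte score covariate the cholesterol and mural lists lost their calls (adjusted p = 0.0534 and 0.212), with means of 0.166 and 0.895 against 0.259 and 1.04 without it. The oocyte list, from which that score is made, then had a mean of 0.0124 (0.461). Of the list members named for 8 h, Nr4a1, Nrip1 and Prlr lost their calls in 5 of 6 leave-outs (highest adjusted p = 0.156, 0.23 and 0.145) and Akr1c18 in 4 (0.185). Nrip1 did not pass with the replicate block either (adjusted p = 0.0505). Grn and Id1 lost theirs in 3 (0.0697 and 0.0962), Vcan in 2 (0.0617), and Fdx1 and Smad6 in 1 (0.0647 and 0.0684).

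After 12 h Has2 and Ptx3 were again lower in PCI. Has2 was at 22.6 ± 3.2 CPM in PCI and 108 ± 32.7 CPM in CTL (SD, n = 3 each) and fell by 2.25 ± 0.36 on the log2 scale (± SE, adjusted p = 0.00256). Ptx3 was at 67.9 ± 24.3 and 476 ± 64 CPM and fell by 2.81 ± 0.34 (0.000175), and Ptges fell by 1.49 ± 0.25. These were the 3 genes of the expansion list called, all lower (4 lower and 1 higher adjusted over the list alone). The list had adjusted p = 0.00477, and adjusted p = 0.274 with an estimated correlation. Tnfaip6, Ptgs2, Areg, Ereg, Gdf9, Bmp15, Furin, Pcsk5, Pcsk6 and Amh had log2 fold changes of -0.39, 0.21, 0.13, -0.05, 0.44, 0.49, -0.29, 0.54, -0.42 and 0.32 and did not pass (adjusted p at least 0.602). The largest rises were in Adh7 and Adh1 (5.49 ± 1.09 and 4.66 ± 1.02), Igfbp5 (4.09 ± 0.69, 733 ± 380 against 43.1 ± 19.5 CPM) and the potassium channel gene Kcnj16 (4.08 ± 0.92). They were followed by the metalloprotease inhibitor gene Timp4 (3.86 ± 0.65), Prlr (3.70 ± 0.39, 123 ± 82.3 against 9.43 ± 0.103 CPM), Rasal1 (3.47 ± 0.52) and the growth factor gene Pdgfd (3.44 ± 0.42). The largest falls were in the receptor gene Gpr83 (-4.77 ± 0.53), Cd52 (-4.46 ± 0.77), the proteoglycan gene Cspg4 (-3.99 ± 0.61), and Slc22a22 (-3.93 ± 0.66). Others were in Acvrl1, a type I receptor of the BMP family (-3.79 ± 0.74), Vwa5b1 (-3.71 ± 0.45), Pkd1l2 (-3.68 ± 0.91) and Anxa8 (-3.63 ± 0.74). In total 361 genes were called, 107 higher and 254 lower. The count was 109, 235 and 191 without CTL replicates 1, 2 and 3 and 212, 228 and 123 without PCI replicates 1, 2 and 3. With only these 6 libraries in the fit it was 767, and DESeq2 called 683. Of the genes with the largest changes, Pkd1l2, Kcnj16, Anxa8, Adh1, Acvrl1 and Adh7 lost their calls in 6, 5, 4, 3, 3 and 2 of the 6 leave-outs (highest adjusted p = 0.182, 0.161, 0.0963, 0.132, 0.0642 and 0.0827).

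The list with the smallest p at 12 h held chaperones and folding enzymes of the endoplasmic reticulum. All 15 of its genes had lower means in PCI, and 2 were called (13 adjusted over the list alone), with a mean log2 fold change of -0.651. It had adjusted p = 3.24e-12, and adjusted p = 0.274 with an estimated correlation. Creld2 fell by 0.79 ± 0.14 and Pdia4 by 0.76 ± 0.19. Hspa5 and Manf, at -0.89 ± 0.24 and -0.98 ± 0.26, did not pass over all genes (adjusted p = 0.0675 and 0.0599). The BMP-SMAD1/5 list was lower, with Id4 and Smad7 called, at -1.78 ± 0.35 and -0.74 ± 0.18 (4 adjusted over the list alone). For it adjusted p = 0.0025, and adjusted p = 0.274 with an estimated correlation. In the SMAD2/3 list Smad7 and Ldlrad4, at -1.35 ± 0.29, were called (4 adjusted over the list alone). That list had adjusted p = 0.0151, 0.0737 without PCI replicate 1, and adjusted p = 0.274 with an estimated correlation. Of 20 integrin, cadherin and junction genes, Itga5 and Itgb5 fell, by 0.88 ± 0.20 and 1.18 ± 0.21 (4 lower and 1 higher adjusted over the list alone). Here adjusted p = 0.0025, and adjusted p = 0.274 with an estimated correlation. Of 22 immediate-early and ERK feedback genes, Jun, Egr2, Egr3 and Dusp5 fell (5 lower and 1 higher adjusted over the list alone). This list had adjusted p = 0.00578, 0.113 without CTL replicate 2, and adjusted p = 0.274 with an estimated correlation.

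Steroid synthesis was higher at 12 h too, with Cyp11a1 at 3.11 ± 0.74 and Nr5a2 at 1.38 ± 0.24 (2 higher and 1 lower adjusted over the list alone). It had adjusted p = 0.0025, and adjusted p = 0.421 with an estimated correlation. In the mural granulosa list Prlr and Cyp11a1 rose (3 higher and 1 lower adjusted over the list alone). Here adjusted p = 0.00578, and adjusted p = 0.274 with an estimated correlation. The oocyte list was higher, in 29 of 30 means, with 0 genes called by edgeR (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). It had adjusted p = 0.0025, 0.0621 without PCI replicate 1, and adjusted p = 0.845 with an estimated correlation (range over all alternatives 1.64e-05 to 0.991). With the added oocyte score covariate 805 genes were called at 12 h, 376 higher and 429 lower. With that covariate the expansion, ERK and SMAD2/3 lists lost their calls (adjusted p = 0.0892, 0.0593 and 0.0936). Their means were -0.378, -0.303 and -0.428 with it and -0.504, -0.333 and -0.427 without. Of the list members named for 12 h, Itga5 and Egr3 lost their calls in 6 of the 6 leave-outs (highest adjusted p = 0.146 and 0.21) and Smad7, Cyp11a1 and Pdia4 in 5 (0.177, 0.2 and 0.174). Egr2 and Ldlrad4 lost theirs in 4 (0.167 and 0.093), Jun and Dusp5 in 3 (0.0716 and 0.0882), and Id4 and Creld2 in 1 (0.0731 and 0.0524).

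**Figure D3:**
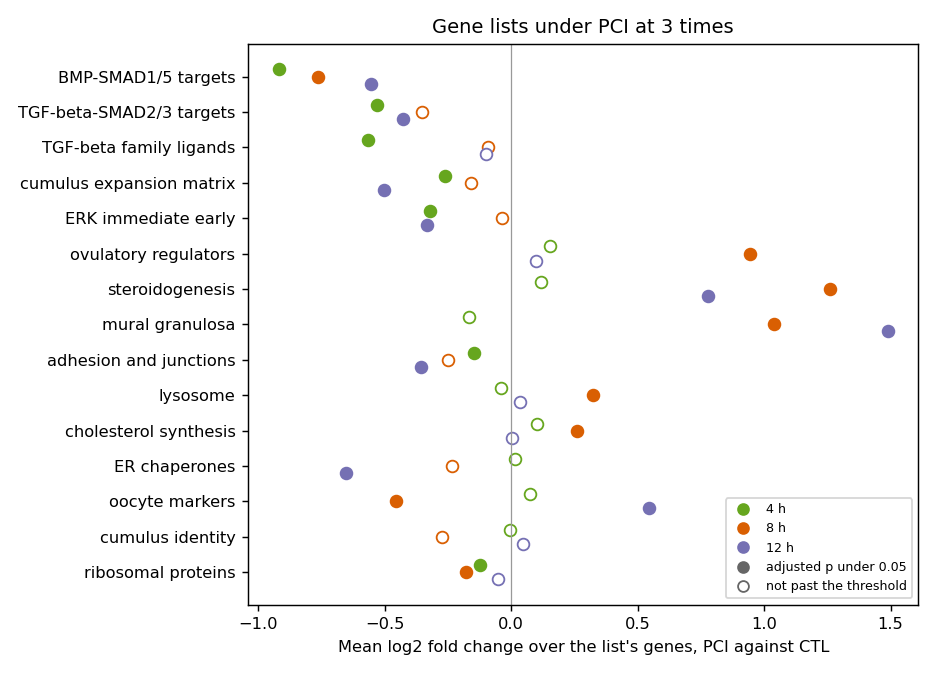
Mean log2 fold change (PCI against CTL) over the measured genes of 15 lists at 4, 8 and 12 h, 3 libraries per group; filled points are lists with a camera adjusted p under 0.05 at the preset correlation of 0.01. The BMP-SMAD1/5 list is lower at all 3 times (-0.919, -0.763 and -0.554) and steroid synthesis higher at 8 and 12 h (1.26 and 0.778), with adjusted p = 0.00188, 0.184 and 0.274 and adjusted p = 0.269 and 0.421 with an estimated correlation.

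Averaged over the 3 times, 1104 genes differed between PCI and CTL, 460 higher and 644 lower. Smad7 and Id4 fell by 1.21 ± 0.10 and 1.97 ± 0.19 on the log2 scale (adjusted p = 4.41e-06 and 7.24e-06), Ptx3 and Has2 by 1.77 ± 0.19 and 1.86 ± 0.21 (1.14e-05 and 1.52e-05), and Itga5 and Ptges by 1.09 ± 0.12 and 1.30 ± 0.15. Tnfaip6, which passed at no time alone, fell by 0.50 ± 0.14 in this average (adjusted p = 0.0356), but did not pass in 12 of the 18 leave-outs (adjusted p = 0.0108 to 0.0876, the highest without PCI 12 h replicate 3). Ptgs2, Furin, Pcsk5 and Gdf9 did not pass, at -0.17, -0.29, 0.51 and 0.19. Of 12 genes of the BMP-SMAD1/5 list 6 fell (7 adjusted over the list alone), with adjusted p = 2.6e-08, and adjusted p = 0.0282 with an estimated correlation. Of 13 in the SMAD2/3 list 5 fell (6 lower and 1 higher adjusted over the list alone), with adjusted p = 0.000119, and adjusted p = 0.0468 with an estimated correlation. Calls at different times compare different libraries, but share each gene's spread as estimated from all 21 libraries. They are thus not fully independent, and the counts expected of independent calls are only a guide. The calls overlapped more than those counts. Between 8 and 12 h, 66 genes were higher at both (2.08 expected) and 125 lower at both (4.37 expected), with 0 called in opposite directions. Of the 22 genes lower at 4 h, 16 were lower at 8 h (0.379 expected).

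**Figure D4:**
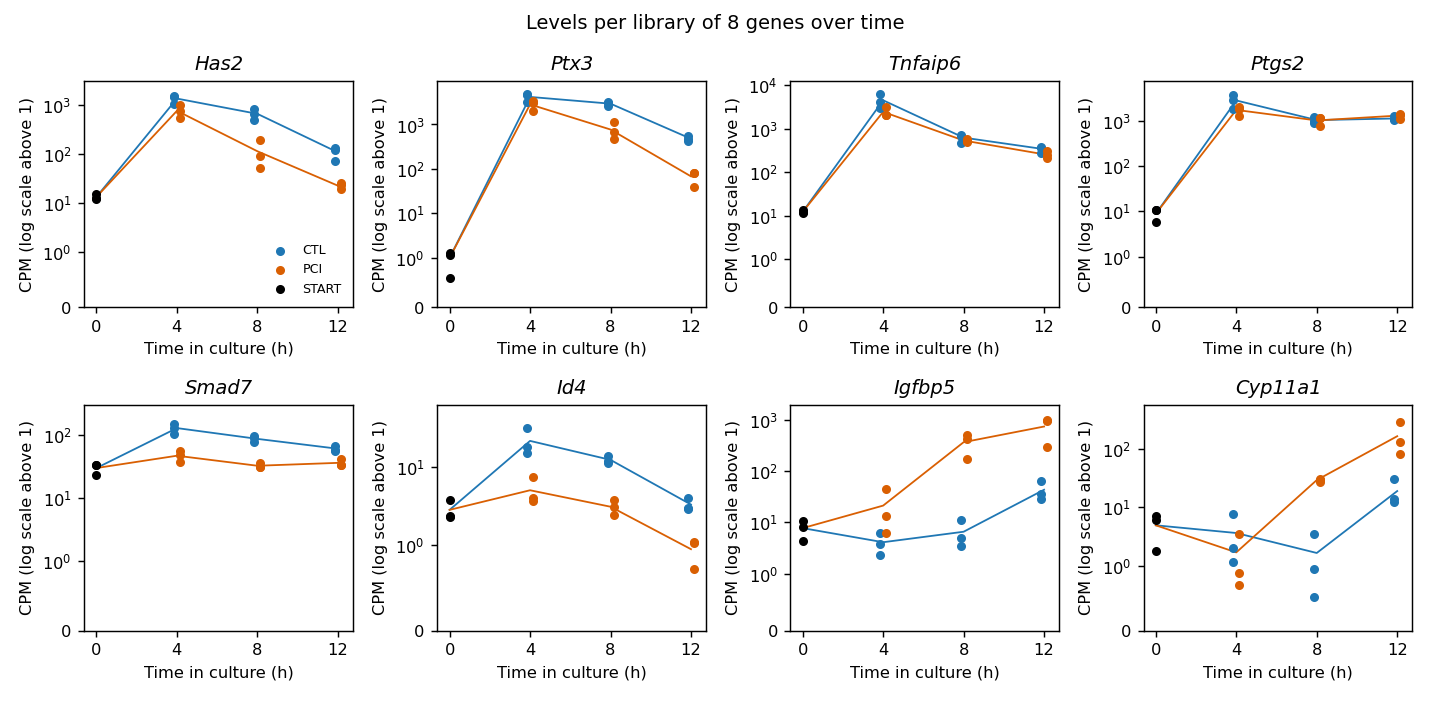
CPM of 8 genes in each library (points) and group means (lines) against time in culture, on an axis that is logarithmic above 1 CPM; black START, blue CTL, orange PCI, 3 libraries each. Has2 and Ptx3 peak at 4 h and lie lower in PCI at 8 and 12 h, Smad7 and Id4 lie lower in PCI at 4, 8 and 12 h, and Igfbp5 and Cyp11a1 lie higher in PCI at 8 and 12 h.

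Whether the PCI effect itself changed with time was tested as an interaction, which called 11 genes (1242 at an unadjusted p under 0.05). Prlr had log2 fold changes of 0.26, 1.53 and 3.70 at 4, 8 and 12 h, and Myc, a growth regulator, of -1.32, 0.73 and 0.71. Neither Has2 (adjusted p = 0.407) nor Ptx3 (0.124) passed, so their smaller differences at 4 h are not shown to differ from those at 8 and 12 h. No gene differed in effect between 8 and 12 h in edgeR's test (0 called, 1133 at an unadjusted p under 0.05). The count of 11 was 0 with edgeR and the replicate block (1310 at an unadjusted p under 0.05), 4 with RLE factors and 185 by DESeq2. It was 36 without PCI 8 h replicate 3 and 19 without PCI 4 h replicate 2. By edgeR it was 0 (996 to 1298 at an unadjusted p under 0.05) without any one of CTL 4 h replicate 1, CTL 8 h replicate 3, CTL 12 h replicates 2 and 3, PCI 4 h replicates 1 and 3, and PCI 8 h replicates 1 and 2. The count was 1 without CTL 4 h replicate 3 or CTL 12 h replicate 1, 2 without CTL 8 h replicate 1, and 5 and 3 without PCI 12 h replicates 2 and 3.

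The PCI effect was also asked of the genes that moved during control maturation, in sets of 200 chosen at another time than the one tested. Genes that rose in CTL by 4 h were lower in PCI at 8 h (mean log2 fold change -0.367, with 6 called higher and 43 lower). Their adjusted p = 2.38e-09, and adjusted p = 0.427 with an estimated correlation. The same set was lower at 12 h (-0.59, 0 and 44), with adjusted p = 2.86e-31, and adjusted p = 0.0114 with an estimated correlation. Genes that rose by 8 h were lower in PCI at 12 h (-0.663, 0 and 52), with adjusted p = 5.54e-39, and adjusted p = 0.00883 with an estimated correlation. They were lower at 4 h (-0.231, 0 and 5), with adjusted p = 3.18e-13, and adjusted p = 0.21 with an estimated correlation. That mean was -0.116 without PCI 4 h replicate 2 (adjusted p = 0.0788) and -0.131 without CTL 4 h replicate 3 (2.23e-05). Genes that fell by 4 h were higher in PCI at 8 h (0.162, 12 and 6), with adjusted p = 0.000205, and adjusted p = 0.621 with an estimated correlation. Their mean was 0.268 without CTL 8 h replicate 2 and 0.0574 with the added oocyte score covariate (adjusted p = 0.0706). Those that rose by 12 h were not called at 8 h (-0.123, adjusted p = 0.114), but were without CTL 8 h replicate 3 (-0.199, 0.00294) or PCI 8 h replicate 1 (-0.131, 0.0459). They were also called with 100 genes in the set (-0.206, 0.00174) and with the added oocyte score covariate (-0.196, 0.0222), while with 400 genes the mean was -0.0237 (0.655). At 12 h, genes that fell by 8 h had a mean of 0.125 (adjusted p = 0.0256, and 0.724 with an estimated correlation). It was 0.134 without CTL 12 h replicate 2 (0.0556) and 0.104 without PCI 12 h replicate 3 (0.103), 0.0687 with 400 genes (0.116) and 0.24 with the added covariate (3.21e-05). Genes that fell by 4 h had a mean of -0.0485 at 12 h (adjusted p = 0.47), which the covariate turned to 0.0803 (0.0241).

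Oocyte RNA was estimated through the oocyte markers, since a COC library holds both cell types. In poly(A)-selected libraries these markers cannot tell a change in the share of oocyte RNA from a change of the marker transcripts within the oocyte. They took 1.75 ± 1.07% of counts in START (SD, n = 3). At 4, 8 and 12 h they took 1.44 ± 0.412, 1.09 ± 0.33 and 0.518 ± 0.0945% in CTL and 1.55 ± 1.02, 0.946 ± 0.192 and 0.709 ± 0.194% in PCI. The log2 ratio of oocyte to cumulus marker counts differed between PCI and CTL by 0.04, -0.52 and 0.55 (exact permutation p = 1, 0.3 and 0.1, two-sided, 0.1 being the smallest that 3 against 3 libraries allow). With the mean log2 CPM over the markers in place of the sum, the differences were -0.08, -0.18 and 0.50 (exact permutation p = 0.9, 0.7 and 0.2). The ratio also moves with the cumulus markers, which fell during control maturation. These took 0.448, 0.316 and 0.181% of counts in PCI and 0.453, 0.251 and 0.194% in CTL (exact permutation p = 0.1 at 8 h). For the percent of oocyte markers alone, exact permutation p was 0.9, 0.6 and 0.2. Within same-numbered pairs the ratio was lower in PCI in 1 of 3 at 4 h and 3 of 3 at 8 h (exact sign-flip p = 1 and 0.25, where 0.25 is the smallest that 3 pairs allow). From the mean log2 CPM it was lower in 2 of 3 at both times (exact sign-flip p = 0.75 and 0.5). Over all times the difference was 0.02 (permutation p = 0.956). Gdf9, the oocyte growth factor gene, was at 1594 ± 441, 1391 ± 330 and 920 ± 208 CPM in CTL and 1708 ± 1160, 1416 ± 230 and 1248 ± 338 CPM in PCI. Markers of other ovarian cell types gave adjusted p = 0.936, 0.831 and 0.124 for stroma, whose test pointed lower at 4 and 8 h while the means were 0.171 and 0.238. Endothelial markers gave 0.681, 0.948 and 0.824, and their test pointed higher at 8 and 12 h while the means were -0.00406 and -0.0202. The list of 9 leukocyte genes was lower in PCI at 12 h, with Cd52 called (1 adjusted over the list alone). Cd52 had 2 counts in START and 874 in CTL at 12 h, while the leukocyte gene Ptprc had 93 and 0. The call of Cd52 thus does not show fewer leukocytes. For the list adjusted p = 0.00477, and adjusted p = 0.274 with an estimated correlation. At 4 and 8 h it was not called (0.835 and 0.991), and a difference between times was not tested for lists. The 3 measured theca markers were higher at 4 and 8 h (adjusted p = 0.0196 and 0.0155, and adjusted p = 0.128 and 0.252 with an estimated correlation). Of these, 0 and 1 were called by edgeR (1 at an unadjusted p under 0.05 at 4 h, 1 and 2 adjusted over the list alone), and the list was not called at 12 h (0.726). The gene called at 8 h was Aldh1a1, at 2.02 ± 0.36. The 4 h call was lost without CTL replicate 2 (adjusted p = 0.166) or PCI replicate 1 (0.218), and the 8 h call with the added oocyte score covariate (0.0564, mean 0.844 against 1.04 without it).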

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

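The tests of the control time course, and of oocyte RNA varying among the 4 h libraries and at 8 h, were chosen after the results were seen, as was the oocyte score covariate. The interaction of PCI with time called 11 genes, and chance is not excluded for that count: 5 of 100 splits of the libraries, the real one included, gave as many. The highest other gave 1808. Each of these 4 other splits exchanged the arms at 8 h, which turns the effect at that time around and so builds in a difference between times, and they are no measure of chance alone. Among the 11, the effect of PCI differed between times for Myc (adjusted p = 0.0311; log2 fold changes -1.32, 0.73 and 0.71 at 4, 8 and 12 h), F3, the tissue factor gene (0.0311; -0.61, 2.34 and 1.04), Rbfox1 (0.0311; 0.13, -0.65 and -1.93), Prlr (0.0388; 0.26, 1.53 and 3.70), Ddit4l (0.0456; -0.67, 3.60 and 1.82) and Nrep (0.0456; -0.37, -1.98 and -2.65), by edgeR. With the replicate block edgeR called 0 genes (1310 at an unadjusted p under 0.05, lowest adjusted p 0.0629, DESeq2 without the block 185). Single libraries that stand apart were not tested for in these groups of 3. At 4 h, PCI replicate 2 differed from replicates 1 and 3 by a chi-square per degree of freedom of 155 and 252, against 50.7 between those replicates.

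The BMP-SMAD1/5 list was lower in PCI at 4 h, by a mean of 0.919 on the log2 scale. A different share of oocyte RNA, as far as the marker-based oocyte score measures it, is argued against. The mean was -0.954 with that score as a covariate (camera adjusted p = 2.72e-11). A single low library is argued against too: over the 6 leave-outs the mean closest to 0 was -0.756, and the highest adjusted p was 5.07e-07. The SMAD2/3 list was lower at 4 h too (mean -0.529) and shares Smad7 and Bambi with this list, so the tables do not single out BMP signals. An effect of the inhibitor on either kind of signal was not tested and stays open.

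Far fewer genes were called at 4 h than at 8 h. If a wider spread at 4 h hid effects of equal size, the 361 genes called at 12 h should have similar effects at both times. The ratio of their median effects at 4 h and 8 h was 0.3 (95% bootstrap interval over genes 0.235 to 0.353), so for these genes the estimates were smaller at 4 h. The interval holds no spread between libraries, and the choice at 12 h leaves out effects present mainly at 4 h. The ratio thus does not decide whether spread hid effects at 4 h. Oocyte RNA varying among the 4 h libraries could also hide calls. With the oocyte score as a covariate the count rose from 24 to 70 at 4 h and from 667 to 1148 at 8 h. Such variation may thus hide some calls at 4 h, but a gap to 8 h stayed. For the counts of 24 and 667, the 10 splits of the 6 libraries are too few for a share under 0.05 (1 split each; the highest others gave 5 and 0).

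Of the 667 genes called at 8 h, 476 (71.4%) differed in the direction of CTL from 4 to 12 h, 343 (51.4%) were also called for that change in CTL and 89 (13.3%) for a change in the opposite direction, against 62%, 31.2% and 13.1% of all 18192 genes. Complexes in PCI that run ahead along the control course could give this. Of the 667 genes, 61 (9.15%) lay beyond all 3 CTL times, under a limit set after the results were seen, so that count decides little. As the only cause, a run ahead is argued against by the principal components. At 8 h PCI scored 32.5 ± 7.84 on the first, between CTL at 8 h (12 ± 14.4) and 12 h (56.5 ± 2.92). On the third it scored -11.8 ± 8.64, against 20.6 ± 1.75 and 15.1 ± 3.48 (SD, n = 3). For part of the genes a run ahead stays open beside a separate effect of the inhibitor. A different share of oocyte RNA, as the oocyte score measures it, is argued against as the source of most calls. With that score as a covariate 660 of the 667 (99%) were called. That fit called 1148 genes at 8 h, so staying called does not show how far effects shrank. Mean log2 fold changes of sets moved both ways, from 0.162 to 0.0574 for genes that fell in CTL by 4 h and from -0.367 to -0.433 for those that rose. Has2 was at 1330, 651 and 108 CPM in CTL at 4, 8 and 12 h and Ptx3 at 4173, 2939 and 476 CPM, so a faster course and a direct loss point the same way for them.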

How the results depend on the processing

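The oocyte score covariate and its tests, and the sign flips of the oocyte ratio within pairs, were chosen after the results were seen. Scaling changed few counts. RLE factors left 7 of 8 counts of genes within 1.5 times, with 4 genes for the change with time, and library size alone left all 8 there. Of the CTL calls at 4 and 12 h, library size alone shared 5363 of 5734 and 8855 of 9286, among 6068 and 9436 of its own, and it moved the median log2 fold change of all genes to -0.172, -0.127 and -0.162 in CTL at 4, 8 and 12 h (TMM -0.0502, -0.0832 and -0.055). Without the filter edgeR called 46 genes at 4 h and 57 for the change with time, of 34717 tested. DESeq2 called 114, 1084 and 683 genes at 4, 8 and 12 h, including 24, 666 and 360 of edgeR's, and 185 for the change with time. With only the groups compared the counts were 0 at 4 h (edgeR; 611 at an unadjusted p under 0.05), 767 at 12 h and 25 for the change with time. With the covariate they were 70, 1148, 805, 1870 for the mean, 143 for the change with time and 6045 for CTL at 12 h (3897 of them shared with the main fit). For each changed count the cause was not tested.

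The replicate block gave 29, 701 and 392 genes for PCI at 4, 8 and 12 h, 1143 for the mean, 5867, 7554 and 9416 for CTL, and 0 for the change with time (edgeR; 1310 at an unadjusted p under 0.05). At 8 h it gained the SMAD2/3 list (adjusted p = 0.0305) and lost glycolysis, oocyte markers and ribosomal proteins (0.0543 each), with the named genes Lama1 and Sc5d gained and Nrip1 lost. At 4 h it lost Itga5 and Olfm2. No other call of a PCI list or named gene at 4 or 8 h changed with the block. At 12 h pairing by number stays open, and the numbers do not pair CTL with START libraries.

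Over single libraries left out, the counts ranged from 3 to 54, 252 to 713, 109 to 235 and 854 to 1353 for PCI at 4, 8 and 12 h and the mean, 0 to 36 for the change with time, and 4872 to 5862, 5857 to 8103 and 7965 to 9820 for CTL. Of the named genes called, 1 of 15, 28 of 50 and 16 of 39 kept their calls in all 6 leave-outs at 4, 8 and 12 h, and 65 of 65, 56 of 57 and 57 of 58 in CTL. Lists called ranged from 7 to 18 for PCI at 4 h. With an estimated correlation 3, 0, 0 and 2 lists were called for PCI and 4, 3 and 2 for CTL, from 12, 12, 10, 12, 14, 12 and 12. With the covariate, made from their own levels, oocyte markers had means near 0 by construction (0.0124 in PCI at 8 h, 0.00871 and -0.0401 in CTL at 8 and 12 h), where camera's direction turned. Reversed lists were, at 4 h, endoplasmic reticulum folding (0.206) and ribosomal proteins (0.0241) without PCI replicate 2 and steroid synthesis (-0.302) and oocyte markers (0.374) without PCI replicate 3 (ranges over leave-outs -0.174 to 0.206, -0.3 to 0.0241, -0.302 to 0.401 and -0.586 to 0.374). For these the cause was not tested.

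Of the sets that moved in CTL, 6 kept their means but lost their calls with an estimated correlation (-0.231, -0.105, -0.044, -0.367, 0.162 and 0.125). With the covariate, genes that fell by 4 h had means of 0.0574 at 8 h and 0.0803, reversed, at 12 h, and genes that rose by 12 h one of -0.196 at 8 h (-0.206 with 100 genes), both now called, and -0.0237 with 400 genes. With 400 genes, those that fell by 12 h had 0.00052 at 4 h and -0.247 at 8 h, and those that fell by 8 h 0.0687 at 12 h. Over leave-outs the means at 4 h ran from -0.336 to -0.116 (rose by 8 h), -0.0317 to 0.0719 (fell by 8 h), -0.207 to 0.011 (rose by 12 h, reversed without PCI replicate 2) and -0.152 to 0.0163 (fell by 12 h); at 8 h from -0.449 to -0.289 (rose by 4 h), 0.11 to 0.268 (fell by 4 h), -0.199 to -0.0574 (rose by 12 h) and -0.181 to -0.104 (fell by 12 h); and at 12 h from -0.606 to -0.571, -0.0697 to -0.0192, -0.698 to -0.641 and 0.0987 to 0.139 (rose and fell by 4 h, rose and fell by 8 h). The cause was not tested. Depth limits genes of few counts, for which folds are bounds.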

Other observations

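The genes of this part were picked, and the test of the stretch on chromosome 11 was chosen, after the results were seen. The list of matrix proteases was not called in PCI at 4, 8 or 12 h (adjusted p = 0.428, 0.239 and 0.588), while single protease genes and regulators were. At 8 h Plau, the urokinase gene, and Adamts9, a protease of versican, rose by 2.13 ± 0.33 and 3.61 ± 0.62 on the log2 scale (SE, n = 3 each), while Plaur, the urokinase receptor gene, fell by 1.80 ± 0.35. At 12 h Mmp14, a membrane metalloprotease gene, and Serpine2, a protease inhibitor gene, fell by 1.15 ± 0.25 and 1.12 ± 0.21. Mmp14 lost its call in 6 of the 6 leave-outs (highest adjusted p = 0.096) and Serpine2 in 1 (0.0566).

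Adm, which encodes the peptide adrenomedullin, rose by 3.62 ± 0.50 at 8 h and 1.89 ± 0.43 at 12 h, and the cytokine gene Lif fell by 2.97 ± 0.47 at 8 h. Spp1 was at 12840 ± 1560 CPM in PCI and 5098 ± 923 CPM in CTL at 8 h without passing the test there (1.33 ± 0.39, adjusted p = 0.0672), and rose by 1.11 ± 0.22 in the mean over the times. Lhcgr, the receptor gene for luteinizing hormone, had 0 counts in CTL and 32 in PCI at 12 h, at least 12.5-fold higher against 3 counts over the group, and did not pass (adjusted p = 0.0944).

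Arhgap27, Plekhm1 and Kansl1, 3 of the 24 genes called at 4 h, lie within 1.2 Mb of chromosome 11 (mm39, 103222323 to 104359687). Of 10000 random gene sets, a share of 0.0074 held as many in a window of that length. Since the window was set from the span of these genes, this decides nothing about chance placement, which stays open. Kansl1 was at 151 ± 21.3 CPM in START, 546 ± 95.3 in CTL and 232 ± 56.3 in PCI at 4 h, and 159 ± 11.8 in CTL at 8 h. The neighbours Gosr2, Nsf, Arf2 and Cdc27 were not called at 4 h (adjusted p = 1 each). Arhgap27 and Plekhm1 are adjacent on the same strand, and whether reads that run past a gene end add to the pattern was not tested.

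Chance is argued against for the mean over the times, where 1 of 100 splits, the real one with 1104 genes, gave as many. This is the smallest share that 100 splits can give. The highest other, with 940 genes, kept 1, 0 and 0 PCI libraries in their arm at 4, 8 and 12 h. It is thus nearly the real grouping with the arms exchanged, and the next highest gave 3. The splits moved libraries freely within a time and did not keep same-numbered pairs. For PCI at 12 h and for CTL at 4, 8 and 12 h the 10 splits are too few for a share under 0.05 (361, 5734, 7506 and 9286 genes; highest other 0 each).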
